A study of Mus musculus with 8 samples.

How the data were processed

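RNA-seq libraries of the medial prefrontal cortex (mPFC) were compared between a retrieval group (4 libraries) and a non-retrieval group (4 libraries) of adult male C57BL/6 mice. Per the labels, each library came from a pool of 2 to 3 mice whose tissue was taken 1 h after the conditioned place preference (CPP) test, RNA was extracted with the RNeasy Micro kit, and libraries were made with the NEBNext Ultra RNA kit. Because the series treats each pool as 1 biological sample, the spread between libraries of a group is a spread between pools of mice. The group and number of each library were taken from its label. The numbers 1 to 4 occur in both groups, and no label says that a number marks a shared litter, cage or day, so they were not used as pairs.

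The deposited values are raw read counts per gene, not normalized, in 1 table of 54532 genes with Ensembl gene identifiers. The submitters' processing notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes and of antisense pairs could not be told apart, and genes with near-identical copies carry an uncertain split of reads. The deposited table also gives the length of each gene model. Counts per library ran from 25013503 to 29547978, and every column of counts was matched to a sample by its title.

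Genes with too few counts were removed with the default filterByExpr setting of edgeR 4.0.16 (R 4.3.3), which left 16745 genes. Library sizes were scaled with TMM factors, and groups were compared with edgeR's quasi-likelihood F test (two-sided) with Benjamini-Hochberg adjustment over all tested genes. A gene was called changed at an adjusted p under 0.05. Log2 fold changes are retrieval over non-retrieval, with their standard errors. CPM (counts scaled to a common library size) were computed with the same factors and are given as mean ± SD over 4 libraries.

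A total of 40 gene lists covering activity-regulated genes, stress and hormone responses, receptors, channels, synapse, chromatin, metabolism, immune genes, and markers of cell types and neighbouring brain regions were tested with camera (limma 3.58.1) at the preset correlation of 0.01, with adjustment over the lists. The lists held 1089 symbols, of which 1082 were found in the table. Camera was repeated with the correlation estimated for each list, and fry was run as another test. The gene lists, tests, covariates, alternatives and the rule for named genes were fixed before the data were examined. Under that rule, the text names the 10 largest rises and 10 largest falls among changed protein-coding genes with a mean CPM of at least 1 and groups that did not overlap, always Fos, Arc, Egr1, Npas4, Nr4a1 and Bdnf, and up to 4 members of each described list with the smallest p. Of the genes this rule selects, 2 are not reported here. Any other gene named was chosen after its values were seen. Library measures were compared with exact two-sided permutation tests of the difference of means over 70 arrangements, whose smallest possible p is 0.0286, adjusted over the measures.

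The comparison was tested on simulated counts drawn from the means, library sizes and dispersions of the real genes. Of genes changed by a log2 fold of 0.3, 22.4% were recovered among 16556 tested genes, against 44% at 0.5, 85.7% at 1 and 97.9% at 2, with 7 false calls among 129. Small changes were therefore often below what 4 libraries per group could detect.

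Alternatives were other scaling factors, other filters, thinned counts, the replicate number as a block, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0, limma-voom with quality weights, other thresholds, and leaving out each library in turn. After the data were seen, a per-library offset for gene length and GC content (loess span 0.5) and the mean log2 CPM of the myelin markers as a covariate were added. GC content came from the GENCODE annotation and sequence of the same build and was available for 16727 of the tested genes (99.9%). Log2 CPM used a prior count of 2. The distinction between transcripts of one gene was not analysed here.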

Results

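The transcriptome of the mPFC was measured in mice after a test of CPP for methamphetamine, a psychostimulant. In CPP, an animal learns to prefer the compartment in which it received a drug, and returning it to the apparatus tests that memory. Of the 8 libraries, 4 came from mice in the retrieval group and 4 from mice in the non-retrieval group, each made from a pool of 2 to 3 mice 1 h after the test. The labels do not say how the non-retrieval mice were handled, so exposure to the apparatus and handling were not separated from retrieval of the memory. Total counts per library ran from 25013503 to 29547978, and 23474 to 24671 genes had at least 1 count.

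The comparison of retrieval with non-retrieval asked which genes differed in the mPFC when the drug-associated memory was retrieved. Activity-regulated genes, among them immediate early genes that neurons transcribe within minutes of activity, were the largest rises in the retrieval group among changed protein-coding genes with a mean CPM of at least 1 and groups that did not overlap. Egr2, a zinc-finger transcription factor, rose most, from 2.51 ± 1.31 CPM (SD, n = 4) to 33.8 ± 4.93 CPM (SD, n = 4), a log2 fold change of 3.74 (SE 0.23). Fos, the AP-1 subunit widely used as a marker of active neurons, rose from 13.1 ± 4.37 to 60.8 ± 4.28 CPM (SD, n = 4; log2 fold change 2.21, SE 0.16). Arc, which regulates AMPA receptor trafficking at synapses, rose from 97.3 ± 42.0 to 431 ± 57.9 CPM (SD, n = 4; log2 fold change 2.15, SE 0.21). The adjusted p was 3.52e-08 for Egr2, 2.24e-07 for Fos and 9.37e-06 for Arc (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and all 4 retrieval libraries lay above all 4 non-retrieval libraries for each of these 3 genes.

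Across all genes, 766 of 16745 tested genes (4.57%) changed, of which 615 were higher and 151 lower in retrieval. Most changes were small, with a median log2 fold change of 0.43 among the higher genes and -0.42 among the lower ones, and 59 genes rose and 13 fell by at least 1 on the log2 scale. The groups did not overlap for 11.1% of tested genes, against 2.86% by chance. An unadjusted p under 0.05 in edgeR was reached by 3096 of the 16745 tested genes, against 837 by chance. Counts of unadjusted p within the gene lists below are to be read against that background. Higher genes made up 80.3% of the calls. With an offset for gene length and GC content, added after the data were seen, 1417 genes were called, of which 775 were higher and 642 lower, so that 54.7% were higher because lower calls were added. The count was 330 without non-retrieval replicate 4, 331 without non-retrieval replicate 3, 397 without retrieval replicate 4, 420 without retrieval replicate 3 and 1360 without retrieval replicate 1. Lower calls numbered 45 without non-retrieval replicate 3 and 328 without retrieval replicate 1. Limma-voom called 1619 genes, 1110 higher and 509 lower.

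**Figure D1:**
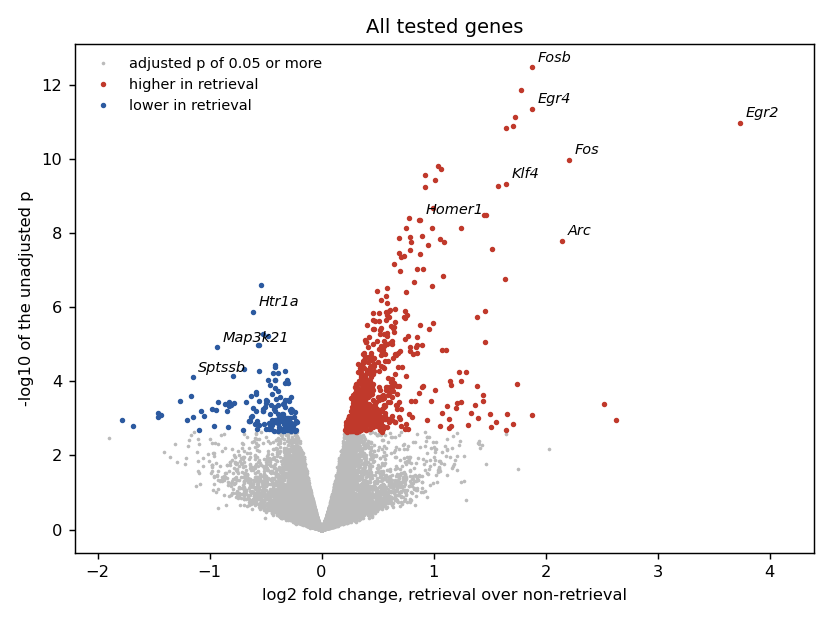
Log2 fold change of each tested gene, retrieval over non-retrieval (x axis), against -log10 of its unadjusted p (y axis, edgeR quasi-likelihood test). Red points are the 615 higher and blue points the 151 lower genes at an adjusted p under 0.05; Egr2 lies farthest right at 3.74.

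The other 7 of the 10 largest rises were Egr4, Fosb, Nr4a3, Egr1, Fosl2, Klf4 and Nr4a2, all of them transcription factors, with log2 fold changes between 1.88 and 1.65. Fosb, whose splice product deltaFosB accumulates with repeated drug exposure, rose from 13.0 ± 1.17 to 47.9 ± 5.07 CPM (SD, n = 4; log2 fold change 1.88, SE 0.09; edgeR adjusted p = 5.67e-09). Egr1 rose by 1.72 (SE 0.10) and Nr4a1, an orphan nuclear receptor, by 1.47 (SE 0.13) on the log2 scale. Bdnf, the neurotrophin linked to synaptic plasticity, rose from 28.4 ± 1.63 to 44.7 ± 5.69 CPM (SD, n = 4; log2 fold change 0.65, SE 0.09; edgeR adjusted p = 0.000339). Npas4, a transcription factor induced by calcium entry into neurons, stood at 21.7 ± 7.0 CPM in non-retrieval and 20.8 ± 2.78 CPM in retrieval (SD, n = 4), a difference within the spread between libraries (log2 fold change -0.06, SE 0.16; edgeR adjusted p = 0.879). In the build GRCm38, Egr2 (ENSMUSG00000037868) lies on chromosome 10 from 67535475 to 67542188, Fos (ENSMUSG00000021250) on chromosome 12 from 85473890 to 85477273, and Arc (ENSMUSG00000022602) on chromosome 15 from 74669083 to 74672570.

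**Figure D2:**
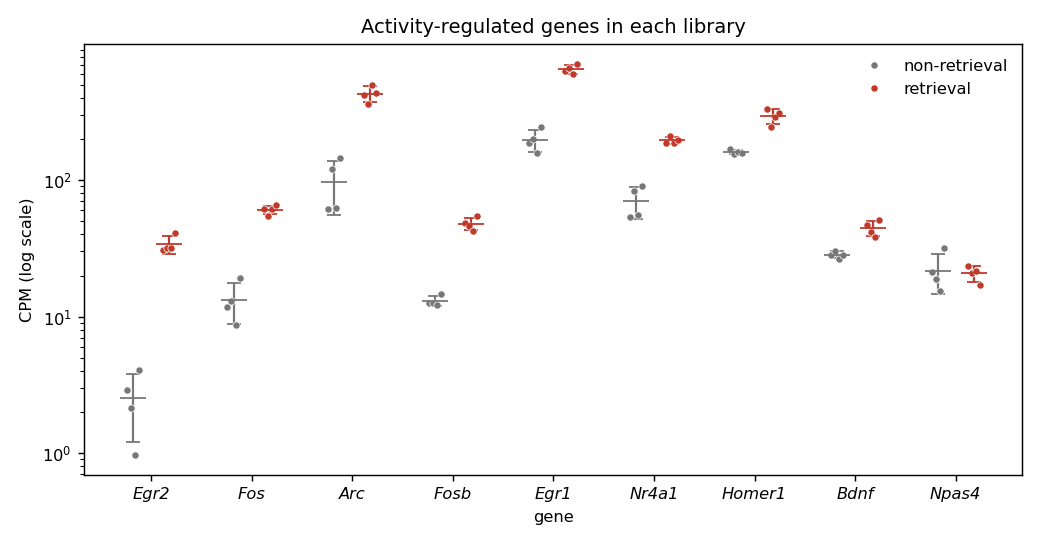
CPM on a log scale (y axis) of 9 activity-regulated genes (x axis) in each library, with points for libraries, horizontal marks for group means and bars for the SD over 4 libraries. The retrieval libraries lie above all non-retrieval libraries for Egr2, Fos, Arc, Fosb, Egr1, Nr4a1, Homer1 and Bdnf, and the groups overlap for Npas4.

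The 10 largest falls were smaller and were found in genes of low abundance. Among them were the zinc-finger gene Zfp969 (log2 fold change -1.16), Sptssb, a subunit of serine palmitoyltransferase (-1.15), Mctp2 (-1.08), the kinase gene Map3k21 (-0.93), Tnfsf10, which encodes the death ligand TRAIL (-0.93), Hfe2 (-0.83), Ripply2 (-0.82), Ucp3, a mitochondrial carrier (-0.82), and Bace2, a relative of the beta-secretase BACE1 (-0.79). Map3k21 went from 5.80 ± 0.84 to 3.02 ± 0.46 CPM (SD, n = 4; edgeR adjusted p = 0.00174) and Bace2 from 5.24 ± 0.80 to 3.03 ± 0.38 CPM (SD, n = 4; edgeR adjusted p = 0.00633). The calls of Sptssb, Map3k21 and Bace2 held with any 1 library left out. Leaving out any 1 of the 8 libraries ended between 1 and 6 of the other calls, at edgeR adjusted p of 0.0504 to 0.150. The most, 6, were lost without non-retrieval replicate 3, followed by 4 without non-retrieval replicate 4 and 4 without retrieval replicate 4.

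Of the 40 gene lists, 14 passed camera at the preset correlation, 13 of them higher and 1 lower in retrieval. With an estimated correlation, 4 of them passed, all higher: the rapid immediate early genes, the delayed activity-regulated genes, the glucocorticoid-responsive genes and the circadian clock genes. At the preset correlation, 7 of the 35 ways to divide the 8 libraries into 4 and 4, the real one included, gave at least 14 lists, and the fewest in another division was 2. With an estimated correlation, no other division gave more than 1 list.

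**Figure D3:**
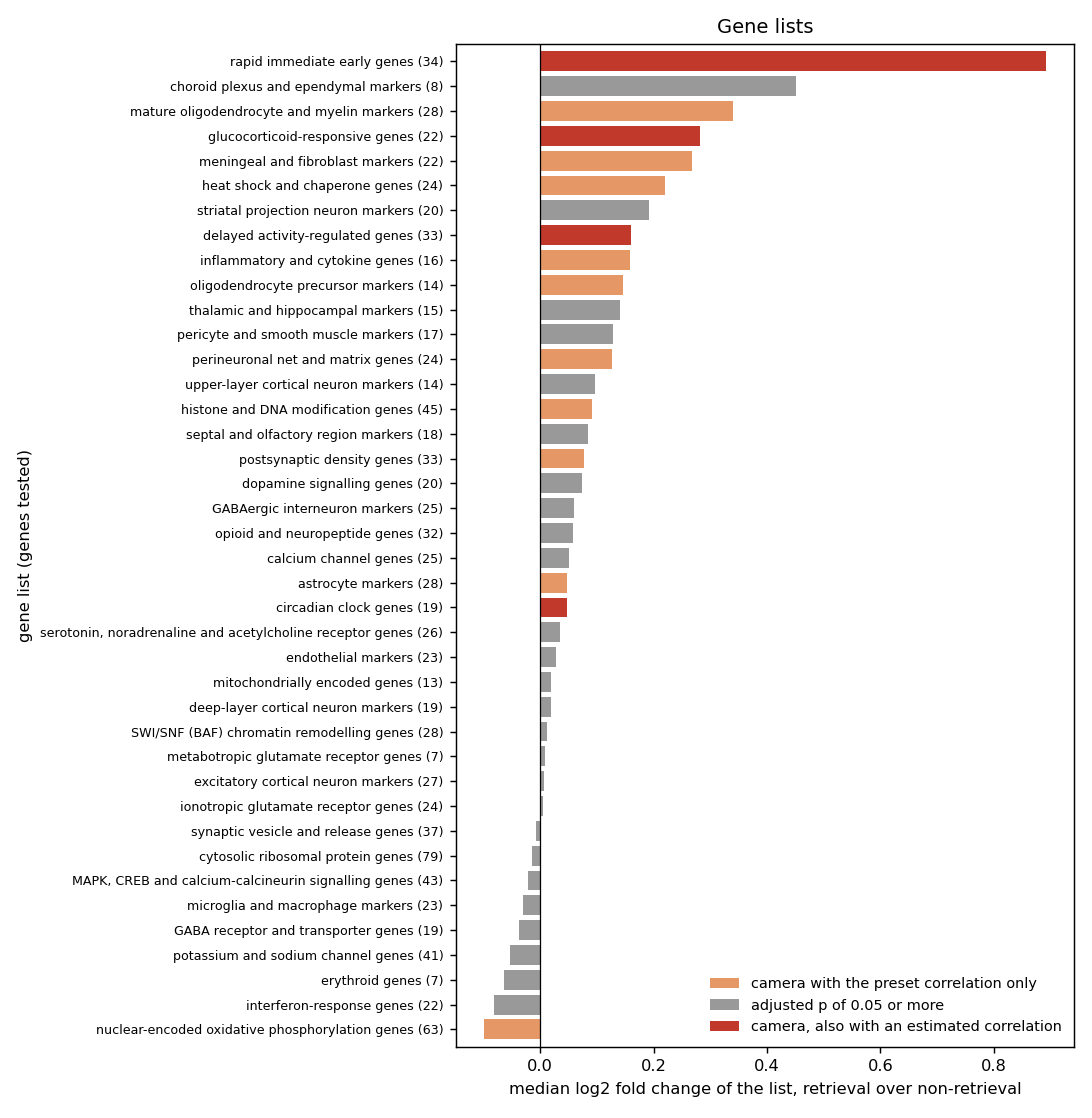
Median log2 fold change, retrieval over non-retrieval (x axis), of each of the 40 gene lists, with the number of tested genes in parentheses. Dark red bars mark the 4 lists past camera also with an estimated correlation, orange bars those past it with the preset correlation only, and grey bars the rest; the rapid immediate early genes have the highest median at 0.89.

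Of 34 rapid immediate early genes, 25 rose and 9 did not pass in edgeR, while 29 were higher and 1 lower when adjusted over the list alone (median log2 fold change 0.89; camera adjusted p = 8.48e-118, and adjusted p = 0.00327 with an estimated correlation). DESeq2 called 26 higher and 1 lower, and limma-voom 28 higher and 1 lower. The 4 members with the smallest p in edgeR were Fosb, Egr4, Egr1 and Egr2. The list of 33 delayed activity-regulated genes holds transcription factors as well as a synaptic scaffold. Of these genes, 10 rose and 23 did not pass, with 12 higher adjusted over the list alone (median 0.16, camera adjusted p = 1.88e-20, and adjusted p = 0.0135 with an estimated correlation). They were led by the nuclear receptors Nr4a3 and Nr4a2, the AP-1 gene Fosl2, and Homer1, a scaffold of metabotropic glutamate receptors. Homer1 rose from 161 ± 6.30 to 296 ± 37.4 CPM (SD, n = 4; log2 fold change 0.88, SE 0.08; edgeR adjusted p = 3.54e-06).

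Of 22 glucocorticoid-responsive genes, 10 rose and 12 did not pass, with 14 higher adjusted over the list alone, and all 22 had a positive log2 fold change (median 0.28; camera adjusted p = 5.03e-19, and adjusted p = 0.00590 with an estimated correlation). Sgk1, a kinase induced by corticosteroids, rose from 47.7 ± 2.37 to 90.3 ± 6.87 CPM (SD, n = 4; log2 fold change 0.92, SE 0.07; edgeR adjusted p = 4.05e-07). Cdkn1a, a cell-cycle inhibitor (0.85), Arl4d (1.08) and Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (0.46), rose as well. Of 19 circadian clock genes, 4 rose and 15 did not pass, with 7 higher and 1 lower adjusted over the list alone (median 0.05; camera adjusted p = 1.38e-05, and adjusted p = 0.0217 with an estimated correlation). With the length and GC offset the circadian list was past the preset test only (adjusted p = 0.000102, but adjusted p = 0.153 with an estimated correlation). Its median was 0.016 without non-retrieval replicate 3, 0.096 without non-retrieval replicate 4, 0.089 without retrieval replicate 1 and 0.11 without retrieval replicate 2, and it passed the preset test in each case. Those 4 were the period genes Per1 (1.07) and Per2 (0.82), and the repressors Bhlhe40 (0.70) and Nfil3 (0.88). Per1 and Nfil3 were also among the rapid immediate early genes, and Cdkn1a among the delayed ones.

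Of 24 heat shock and chaperone genes, 12 rose and 12 did not pass, with 12 higher adjusted over the list alone (median 0.22; camera adjusted p = 1.53e-13, but adjusted p = 0.194 with an estimated correlation). The co-chaperones Dnajb5 (0.78) and Dnajb1 (0.58), the endoplasmic reticulum disulfide isomerase Pdia4 (0.51) and the inducible HSP70 gene Hspa1b (1.39) led the list. Hspa1b shares nearly all of its sequence with Hspa1a, so the split of reads between them is uncertain. Of 45 histone and DNA modification genes, 10 rose and 35 did not pass, with 15 higher adjusted over the list alone (median 0.09; camera adjusted p = 1.37e-06, but adjusted p = 0.194 with an estimated correlation). Among them were the DNA demethylating enzyme gene Tet3 (log2 fold change 0.69, SE 0.07), the histone H3K27 demethylase gene Kdm6b (1.06, SE 0.10), and the H3K4 methyltransferase genes Kmt2a (0.62, SE 0.10) and Setd1b (0.56, SE 0.09). With the length and GC offset the median of this list was 0.01, and 7 of the 10 genes stayed higher. None of 28 genes of the SWI/SNF remodelling complexes changed in edgeR or adjusted over the list alone, although 7 had an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 3.

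Myelin markers were higher in retrieval, and libraries differed in them within groups. All 28 mature oligodendrocyte and myelin markers had a positive log2 fold change, 8 rose and 20 did not pass, and 22 were higher adjusted over the list alone (median 0.34; camera adjusted p = 7.67e-14, but adjusted p = 0.337 with an estimated correlation). The list did not pass fry (adjusted p = 0.132). At the preset correlation of camera it also passed in 20 of the 34 other ways to divide the 8 libraries into 4 and 4. Ermn (0.47), Mal (0.46) and Mobp (0.58), which encode proteins of the myelin sheath or its cytoskeleton, rose. The mean log2 CPM of the list was 6.43 in retrieval replicate 2 and 6.33 in retrieval replicate 4, 5.98 and 5.97 in the other 2 retrieval libraries, and 5.73 to 6.02 in non-retrieval. With that mean as a covariate, added after the data were seen, 273 genes were called in all. Of 14 oligodendrocyte precursor markers, Gpr17 (0.40) and Bcas1 (0.36) rose, also adjusted over the list alone, and 12 did not pass (camera adjusted p = 0.00287, but adjusted p = 0.274 with an estimated correlation). Bcas1 lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 2 or 4 (edgeR adjusted p 0.0691 to 0.107).

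Markers of striatal projection neurons, which lie beneath the mPFC, stood apart in 1 library. Retrieval replicate 2 had a mean log2 CPM of 4.95 over the 20 tested markers, against 4.03 to 4.25 in the other 7 libraries, and its Drd2 level was 7.45 CPM against 1.21 to 2.18 CPM elsewhere. In edgeR none of these markers rose, with 7 higher at an unadjusted p under 0.05, and Scn4b fell, with 5 higher and 1 lower adjusted over the list alone. DESeq2 called 1 higher and 0 lower, and limma-voom 2 higher and 1 lower. Scn4b lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 3 or 4 (edgeR adjusted p 0.0602 to 0.144). Of 20 dopamine signalling genes none changed in edgeR, with 6 at an unadjusted p under 0.05, 2 higher adjusted over the list alone, 1 called by DESeq2 and 3 by limma-voom. The D1 receptor gene Drd1 had a log2 fold change of 0.38 (edgeR adjusted p = 0.0716) and Drd2 of 1.23 (edgeR adjusted p = 0.0720). The same library held most of the signal of Gapdh, a gene chosen after its values were seen. Gapdh stood at 157 CPM in retrieval replicate 2 and 7.24 to 30.6 CPM in the other retrieval libraries (log2 fold change 2.63; edgeR adjusted p = 0.0331). Without that library its log2 fold change was 0.97 (edgeR adjusted p = 0.102), the call also ended without any 1 of the non-retrieval libraries (edgeR adjusted p up to 0.115), and Gapdh has many near-identical pseudogenes, which leaves its count uncertain.

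**Figure D4:**
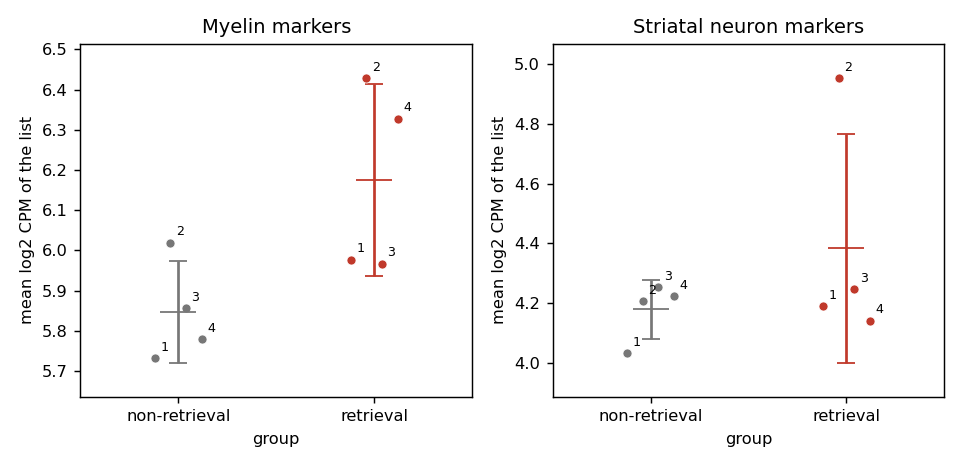
Mean log2 CPM (y axis) of the myelin markers and of the striatal neuron markers in each library, by group (x axis), with points numbered by replicate and bars for the mean and SD over 4 libraries. Retrieval replicate 2 is highest in both, at 6.43 and 4.95.

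Other non-neuronal lists held fewer calls than the myelin list. Of 28 astrocyte markers, Ppp1r3c, which promotes glycogen storage (0.58), Id4 (0.32) and Vim (0.35) rose, also adjusted over the list alone, and 25 did not pass (camera adjusted p = 0.0269, but adjusted p = 0.732 with an estimated correlation). The call of Id4 ended without non-retrieval replicate 4 (edgeR adjusted p = 0.0560). Vim lost its call without non-retrieval replicate 1, 2 or 3 or retrieval replicate 2 or 4 (edgeR adjusted p 0.0533 to 0.0952). The list was lost without non-retrieval replicate 1 or 2 or retrieval replicate 2, 3 or 4, at camera adjusted p of 0.0551 to 0.166. Among 22 meningeal and fibroblast markers, Col1a2 (0.44) alone rose, also adjusted over the list alone (camera adjusted p = 0.0179, but adjusted p = 0.633 with an estimated correlation). This list was lost without non-retrieval replicate 1 or 3 or retrieval replicate 1 or 3, at camera adjusted p of 0.109 to 0.166. Col1a2 lost its call without non-retrieval replicate 1, 2 or 3 or retrieval replicate 3 or 4 (edgeR adjusted p 0.0525 to 0.0929). Slc2a1, the glucose transporter of the blood-brain barrier, rose among 23 endothelial markers (0.53), and Myh11 among 17 pericyte and smooth muscle markers (0.35), and each was the only call adjusted over the list alone. The call of Myh11 ended with any 1 library left out (edgeR adjusted p 0.0556 to 0.132). None of 23 microglia and macrophage markers changed in edgeR or adjusted over the list alone, with 2 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom. None of 8 choroid plexus and ependymal markers did either, although their median log2 fold change was 0.45 (camera adjusted p = 0.0940), with 3 at an unadjusted p under 0.05 and 0 by both other tools, and of 7 erythroid genes Hbb-bs, which shares reads with its near-identical copy, fell (-0.44), also adjusted over the list alone. Hbb-bs lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 2, 3 or 4 (edgeR adjusted p 0.0543 to 0.135).

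Genes for synapses and matrix changed in a few members. Of 33 postsynaptic density genes, Homer1 and Synpo (0.33) rose and 31 did not pass, with 5 higher adjusted over the list alone (camera adjusted p = 0.00194, but adjusted p = 0.260 with an estimated correlation and 0.448 with the length and GC offset at the preset correlation). Synpo lost its call without non-retrieval replicate 3 or retrieval replicate 4 (edgeR adjusted p 0.0609 to 0.0728). Of 24 perineuronal net and matrix genes, Tnc (1.16), Timp3 (0.33), Adamts1 (0.40) and Adamts4 (0.51), the last chosen after its values were seen, rose. Hapln4, a link protein of nets around parvalbumin neurons, fell by 0.33, and 5 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0269, but adjusted p = 0.259 with an estimated correlation and 0.0692 at the preset one without non-retrieval replicate 4). With the length and GC offset its adjusted p was 0.0877. Timp3 lost its call without non-retrieval replicate 4 or retrieval replicate 3 (edgeR adjusted p 0.0525 to 0.0538). The call of Adamts1 ended without retrieval replicate 4 (edgeR adjusted p = 0.0566). Adamts4 lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 2 or 4 (edgeR adjusted p 0.0530 to 0.126). Of 37 synaptic vesicle and release genes, Syt2, the calcium sensor of fast inhibitory terminals (-0.42), and Vamp1 (-0.33) fell, Bsn (0.33) and Doc2b (0.33) rose, and 2 were higher and 3 lower adjusted over the list alone. Vamp1 lost its call without non-retrieval replicate 3 or 4 (edgeR adjusted p 0.0609 to 0.0672). Bsn lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 2, 3 or 4 (edgeR adjusted p 0.0752 to 0.129). The call of Doc2b held only without retrieval replicate 1 (edgeR adjusted p 0.0591 to 0.155 otherwise).

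Receptor genes moved in both directions. Of 26 serotonin, noradrenaline and acetylcholine receptor genes, the muscarinic receptor gene Chrm4 (log2 fold change 0.60, SE 0.08) and the serotonin receptor gene Htr4 (1.12, SE 0.26) rose, while Htr1a (-0.61, SE 0.08) and Chrm3 (-0.31, SE 0.06) fell, and 4 were higher and 3 lower adjusted over the list alone. Htr1a, the inhibitory serotonin receptor gene, went from 25.9 ± 2.03 to 17.0 ± 1.06 CPM (SD, n = 4; edgeR adjusted p = 0.000378). Of 32 opioid and neuropeptide genes, the somatostatin receptor gene Sstr2 rose (0.37) and Sstr1 (-0.29) and the kappa opioid receptor gene Oprk1 (-0.50) fell, also adjusted over the list alone. Htr4 lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 3 or 4 (edgeR adjusted p 0.0569 to 0.0672). Sstr2 lost its call without non-retrieval replicate 3 or 4 or retrieval replicate 3 or 4 (edgeR adjusted p 0.0525 to 0.0747). Sstr1 lost its call without non-retrieval replicate 2, 3 or 4 or retrieval replicate 1, 3 or 4 (edgeR adjusted p 0.0515 to 0.139). Oprk1 lost its call without non-retrieval replicate 2 or retrieval replicate 3 or 4 (edgeR adjusted p 0.0577 to 0.0683). None of 24 ionotropic and none of 7 metabotropic glutamate receptor genes changed in edgeR or adjusted over the list alone, with 3 and 1 at an unadjusted p under 0.05, 0 and 0 called by DESeq2, and 0 and 1 by limma-voom. None of 19 GABA receptor and transporter genes changed in edgeR, with 1 higher adjusted over the list alone, 3 at an unadjusted p under 0.05, 1 by DESeq2 and 4 by limma-voom. Ryr3, an intracellular calcium release channel, rose among 25 calcium channel genes (0.67), of which 5 were higher adjusted over the list alone. The potassium channel gene Kcns2 (-0.29) and the sodium channel gene Scn4b (-0.47) fell among 41 potassium and sodium channel genes, also adjusted over the list alone. Kcns2 lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 2, 3 or 4 (edgeR adjusted p 0.0684 to 0.115). Scn4b lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 3 or 4 (edgeR adjusted p 0.0602 to 0.144).

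Neuronal identity markers changed little. Pvalb, the calcium-binding protein of fast-spiking interneurons, fell by 0.41 and Nos1 rose (0.42) among 25 GABAergic interneuron markers, with 2 higher and 1 lower adjusted over the list alone. Pvalb lost its call without non-retrieval replicate 2, 3 or 4 or retrieval replicate 2 or 4 (edgeR adjusted p 0.0576 to 0.148). Nos1 lost its call without non-retrieval replicate 1, 3 or 4 or retrieval replicate 2, 3 or 4 (edgeR adjusted p 0.0561 to 0.141). Ctgf rose (0.66) among 27 excitatory neuron markers and, with a fall of Oprk1, among 19 deep-layer markers, and these were the only calls adjusted over the list alone. The call of Ctgf ended without non-retrieval replicate 4 (edgeR adjusted p = 0.0796). Oprk1 lost its call without non-retrieval replicate 2 or retrieval replicate 3 or 4 (edgeR adjusted p 0.0577 to 0.0683). None of 14 upper-layer markers, 18 septal and olfactory markers or 15 thalamic and hippocampal markers changed in edgeR, with 4, 1 and 2 at an unadjusted p under 0.05, 0, 0 and 1 called by DESeq2, 3, 0 and 2 by limma-voom, and 0, 0 and 1 higher adjusted over the list alone.

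Of 63 nuclear genes for oxidative phosphorylation, none passed in edgeR or adjusted over the list alone. Only 8 had a positive log2 fold change, and the list was lower (median -0.10, camera adjusted p = 4.59e-05, but adjusted p = 0.601 with an estimated correlation). With the length and GC offset the median of these genes was -0.060 (camera adjusted p = 0.0257 at the preset correlation). Of these 63 genes, 12 had an unadjusted p under 0.05, against 3096 of all 16745 tested genes. DESeq2 called 1 of the 63 and limma-voom 0, and Atp5g3 and Sdhb had the smallest p (log2 fold change -0.16 and -0.17). None of 13 mitochondrially encoded genes changed in edgeR or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 by both other tools. Rpl17, whose pseudogenes leave its count uncertain, was the only one of 79 cytosolic ribosomal protein genes that fell in edgeR (-0.81), also adjusted over the list alone. Rpl17 lost its call without non-retrieval replicate 1 or 4 or retrieval replicate 3 (edgeR adjusted p 0.0508 to 0.0755). Of 16 inflammatory and cytokine genes, the prostaglandin synthase gene Ptgs2 (0.76), Nfkbia (0.58) and Stat3 (0.23) rose, also adjusted over the list alone (camera adjusted p = 0.0204, but adjusted p = 0.194 with an estimated correlation and 0.0593 at the preset one without retrieval replicate 1). The call of Stat3 held only without retrieval replicate 1 (edgeR adjusted p 0.0760 to 0.163 otherwise). The call of Nfkbia ended without non-retrieval replicate 3 (edgeR adjusted p = 0.0562). Irf9 rose among 22 interferon-response genes (0.50), also adjusted over the list alone. Irf9 lost its call without non-retrieval replicate 3 or 4 or retrieval replicate 3 (edgeR adjusted p 0.0528 to 0.0573). Of 43 MAPK, CREB and calcium-calcineurin signalling genes, Srf, a transcription factor that drives immediate early genes, rose (0.46), and 3 were higher adjusted over the list alone. Camera adjusted p for the 26 lists that did not pass ran from 0.0940 to 0.983. In 4 of them, the synaptic vesicle, ionotropic glutamate receptor, metabotropic glutamate receptor and MAPK lists, the median, the mean and the direction of camera differed in sign, with medians of -0.0080, 0.0046, 0.0086 and -0.021.

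Library composition was also compared. No measure passed adjustment in exact permutation tests, whose smallest possible p of 0.0286 leaves little room with 6 measures. Genes detected numbered 24214 ± 373.7 in retrieval and 23633 ± 224.5 in non-retrieval (SD, n = 4; exact permutation p = 0.0571, adjusted p = 0.171). Haemoglobin transcripts made up 0.00481% ± 0.00048 of counts in retrieval and 0.00609% ± 0.00074 in non-retrieval (SD, n = 4; exact permutation p = 0.0571, adjusted p = 0.171). Mitochondrially encoded genes took 3.31% ± 0.301 and 3.24% ± 0.267 of counts (SD, n = 4; exact permutation p = 0.714, adjusted p = 0.886). The adjusted exact permutation p was 0.886 for total counts, 0.857 for the share of ribosomal protein genes and 0.886 for the share of the 10 most abundant genes.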

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

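Tests chosen only after the result was seen were those of white matter, of fewer interneurons, of the surplus of higher calls and of retrieval replicate 2 alone in their present form, of the median and of the calls of the histone and DNA modification genes, and of the splits with an estimated correlation. The length and GC offset and the myelin covariate were also added after the data were seen. The bound of the test for fewer interneurons was changed after its value was seen, and under the bound first set that value would have argued against fewer interneurons. The test for the surplus was first on the share of higher calls alone, and under that bound the trend would have accounted for it. The test for retrieval replicate 2 alone first set no requirement on the spread, and under that bound its value would have argued against it. A first test of striatal tissue used the markers in which it was noticed and was replaced by genes whose values had not been seen. The test of the histone and DNA modification genes was first 1 test of the whole list and was divided into its median and its calls after the list's values were seen. Of 262 groups of 4 libraries checked for a library far from the other 3, 17 held one, against 13.1 that chance gives at about 1 in 20 groups.

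The splits of the 8 libraries bear on the counts of calls. Only the real split of the 35 called as many as 766 genes (1 of 35, the smallest share possible), and the highest count in another split was 2. Chance assignment of the libraries to groups is therefore unlikely to give the count of genes, though 35 splits cannot exclude it. For gene lists at the preset correlation, 7 of the 35 splits called at least 14, and the highest other split called 16. That split put 1 retrieval library with non-retrieval libraries, and the rapid immediate early genes still passed in it. Such a split keeps part of the real contrast, so the splits cannot decide whether chance gives the count of lists. Splits with 2 retrieval libraries on each side balance the groups, and they still called from 2 to 10 lists. Passing the preset test alone therefore does not tie a list to retrieval. With an estimated correlation the real split called 4 lists, as many as no other split did (1 of 35), and the highest other called 1. Chance is therefore unlikely to give that count but cannot be excluded, and this version was chosen after the result was seen.

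The libraries that stood apart were the following. Egr2 was 41.2 CPM in retrieval replicate 4, against 30.6 to 31.9 CPM in the other retrieval libraries. Cdkn1a (39.8 CPM), Nfil3 (13.2 CPM), Dusp4 (23.5 CPM) and Rpl17 (38.1 CPM) were also above the rest in retrieval replicate 4. Retrieval replicate 2 stood apart in Gapdh (157 CPM), Homer2 (69.5 CPM) and Myd88 (4.19 CPM), the last 2 being low. Retrieval replicate 1 was low in the mean log2 CPM of the astrocyte markers (6.63) and in Slc2a1 (111 CPM), and retrieval replicate 3 in Ermn (41.3 CPM). Non-retrieval replicate 2 was high in the mean log2 CPM of the postsynaptic density genes (7.85) and in Oprk1 (9.61 CPM), and non-retrieval replicate 4 in Sptssb (3.13 CPM), Dusp6 (65.7 CPM) and Ptgds (211 CPM) and low in Irs2 (58.6 CPM).

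Myelin markers were higher in retrieval by a median log2 fold change of 0.34, and striatal markers were higher in retrieval replicate 2. Whether retrieval replicate 2 was the only source of the myelin difference stays open. Without it the median was 0.26 (camera adjusted p = 1.84e-09 at the preset correlation and 0.550 with an estimated one). The estimated correlation cannot decide it, because the list had a camera adjusted p = 0.337 there with all libraries. Retrieval replicate 4, at a mean log2 CPM of 6.33, lay above the non-retrieval range (5.73 to 6.02), and retrieval replicates 1 and 3 within it. White matter taken up unevenly in dissection may account for the myelin difference, but this was not shown. The markers moved together between libraries within groups, with an estimated correlation of 0.724. Markers of the same cells would also move together if the oligodendrocytes themselves differed, so the correlation cannot tell these cases apart. Striatal tissue in the pool of retrieval replicate 2 may account for its striatal markers, which were a median of 0.56 above the other 3 retrieval libraries on the log2 scale: 12 other striatal genes, in no fixed list and not looked at before, were above them by a median of 0.39, at percentile 100 of random lists matched on expression (95th percentile 0.14), though all libraries expressed the fixed markers, the other 7 at a mean log2 CPM of 4.03 to 4.25. A change of oligodendrocytes with retrieval was not tested and stays open.

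Long genes were higher in retrieval: of the 1675 longest genes 158 were higher and 4 lower, against 124 and 144 with the offset, and of the 1675 shortest 14 and 12. A trend with length and GC content between libraries was tested as the whole cause of the higher calls among the histone and DNA modification genes. Of the 10 genes called higher, 7 stayed higher after the offset, and the 10 had a median log2 fold change of 0.32 against 0.48 before. This is weak evidence against such a trend, because the 10 were chosen as calls and 698 of all 766 calls were kept with the offset. The list, still past the preset camera test (adjusted p = 0.00297), had an adjusted p = 0.172 with an estimated correlation. Such a trend may account for the higher median of that list, which went from 0.091 to 0.012 with the offset. Whether it accounts for the surplus of higher calls stays open: the share of higher calls went from 80.3% to 54.7%, but because lower calls went from 151 to 642, while higher calls went from 615 to 775. The per-library slope of log2 expression on log2 length ran from -0.00034 to 0.033 in retrieval and from -0.031 to 0.0016 in non-retrieval. Its mean was 0.0127 in retrieval and -0.0127 in non-retrieval. The groups overlapped in a single pair of libraries (exact permutation p = 0.0571), so a trend that varies between libraries regardless of group is not excluded. In simulated counts with no changed gene, a length trend between the groups (slope 0.050) gave 0 calls without the offset. With no changed gene the adjusted threshold is stricter than among 766 calls. The simulation therefore cannot say whether such a trend adds higher calls in the real data. A difference in transcription or RNA decay of long genes stays open and untested.

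A group of 7 genes typical of parvalbumin interneurons, noticed as calls in the data, was lower in retrieval: Pvalb, Syt2, Hapln4, Scn4b, Vamp1, Nefm and Kcns2, of which 6 belong to the fixed lists. All 7 stayed lower after the length and GC offset, with a median log2 fold change of -0.36 against -0.33 before. They were chosen as calls, 698 of all 766 calls were kept with the offset, and lower calls went from 151 to 642. Their staying lower is therefore only weak evidence against a length and GC trend. A change across genes typical of these cells stays undecided: 10 such genes not looked at before had a median log2 fold change of -0.082, 8 being negative (fry p = 0.0338, camera p = 0.0226 at the preset correlation and 0.135 with an estimated one), and with the offset a median of -0.18 with 3 called lower. Without the offset 1 of them, Kcnab3, was called, and its call ended without non-retrieval replicate 1, 3 or 4 or retrieval replicate 4 (edgeR adjusted p 0.0530 to 0.110). Fewer cells of this class in the retrieval tissue cannot be told apart from lower expression within them. A set of 7 interneuron identity genes had a median of -0.049, or -0.021 without retrieval replicate 2, and a mean of -0.030 (SE 0.031). With the offset their median was -0.056, and 2 of the 7 were called lower. These identity genes are shared with other interneurons, so they cannot separate the cases. Lower expression within parvalbumin interneurons was not tested apart from their number and stays open. The calls of Pvalb, Scn4b, Vamp1, Nefm and Kcns2 each ended without non-retrieval replicate 3 or 4, at edgeR adjusted p of 0.0553 to 0.148 over all libraries that ended them.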

How the results depend on the processing

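The length and GC offset and the myelin covariate were chosen after the data were seen. The count of 766 changed genes stayed within 1.5 times under other scaling factors, filters, thinned counts, 1 surrogate variable and DESeq2 (657 to 1139). It was 1619 with limma-voom and quality weights, 1173 at an adjusted p under 0.1, 291 with an absolute log2 fold change of at least 0.5, 1417 with the length and GC offset and 273 with the myelin covariate; the looser and stricter thresholds move it by construction, and for the others the cause was not tested. With 1 library left out it ran from 330 to 1360. With the replicate number as a block it was 1791, holding all 766 genes. No label says that the numbers pair the libraries, so pairing stays open. Deviations of same-numbered libraries correlated at 0.221, 0.0850, 0.0268 and 0.0996, not all over 0.1. All 8 libraries correlated best with their own number, a hint from the data and not from the design. Under the replicate block the same 14 lists passed. The count of 14 lists was 4 with an estimated correlation and 11 with fry, stayed between 10 and 18 under the other settings, and ran from 12 to 16 with 1 library left out. Of the 14, fry kept 10, losing the myelin, oxidative phosphorylation, meningeal and astrocyte lists, and gained the thalamic and hippocampal markers. The offset kept 12 and gained the potassium and sodium channel genes (median -0.085, camera adjusted p = 0.000111) and the synaptic vesicle genes (median -0.079, camera adjusted p = 0.0125), both lower, but with adjusted p = 0.196 and 0.154 with an estimated correlation. The myelin covariate kept 9, losing the myelin, postsynaptic density, oligodendrocyte precursor, astrocyte and perineuronal net lists and gaining the upper-layer markers, and 212 of its 273 genes were among the 766. Under the myelin covariate the median of the myelin markers turned to -0.039 by construction, Gfap, not called, to -0.073 and Npas4 to 0.19. With 1 library left out Npas4, never called, ran from -0.20 to 0.18, and was positive without non-retrieval replicate 4 (0.18) and without retrieval replicate 4 (0.023). For the 111 named genes, 73 of 1553 values under settings other than leaving out a library lost the call with the same direction and 17 gained it, as did 149 and 4 of 888 with a library left out. The number of library measures past adjustment was 0 in every case, but tests of 3 against 4 libraries have too few arrangements to show stability. At this depth and n, few changes of 0.3 on the log2 scale could be detected (22.4% of simulated ones), so genes that were not called may still differ by that much.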

Other observations

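The gene group described first was chosen after its values were seen, and so were the tests of it. Of 21 genes that restrain ERK signalling, 9 rose, none fell and 12 did not pass (edgeR quasi-likelihood test), and 1 of the 21 had a negative log2 fold change. Of those 21 genes, 5 belong to the fixed lists, and 5 of the 9 that rose belong to none of them. The ERK phosphatase genes Dusp4 (1.09), Dusp5 (0.98), Dusp6 (0.79) and Dusp1 (0.79), the Sprouty gene Spry4 (0.90), Spred2 (0.38) and the EGF receptor inhibitor gene Errfi1 (0.34) were among them. The median log2 fold change of the group was 0.24 (camera p = 0.000658 with an estimated correlation, not adjusted). With the length and GC offset 11 of the 21 were called higher.

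Most changed genes lay outside the fixed lists: 515 of the 615 higher and 139 of the 151 lower genes. Among them, named after their values were seen, Irs2, an adaptor of the insulin receptor (log2 fold change 1.04), Nab2, a repressor that binds EGR factors (0.79), Klf10 (0.87), Gadd45a (1.00) and Ccnd2 (0.71) rose. Rasgef1b, a Ras family exchange factor, fell by 0.54.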
